A study of Mus musculus with 2 samples.

How the data were processed

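Single-cell RNA sequencing libraries were made from ILC2 sorted by surface markers from the meninges and choroid plexus of IL-33 treated aged mice with the 10x Genomics 5' gene expression kit, per the labels' protocols. Each tissue gave 1 library, and the number of mice behind a library is not given in the sources used here. The deposited matrices hold raw UMI counts per gene row and cell, produced by the authors with Cell Ranger and STAR on the mm10 build, per the submitters' processing notes. These notes name Cell Ranger 3.1.0, while the matrices give software version 3.0.2, per the file headers. The annotation release is not given in the sources used here. Cells had been called before deposit: the fewest UMIs of any barcode were 500 in the meninges and 502 in the choroid plexus matrix. The matrices number 31053 gene rows and pair no names with them, and names were not inferred from the order of any annotation. That the row numbers mean the same genes in both libraries was checked on the values: the Spearman rho between the libraries was 0.91 over 2259 rows, and -0.01 when 1 library was shifted by 1 row. The barcode list of the meninges library holds no measurement and was not used.

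Barcodes with fewer than 500 detected genes were left out (29 in the meninges, 33 in the choroid plexus). The sum of UMIs over the kept cells was 7078487 in the meninges and 15747765 in the choroid plexus, and a count of 3 corresponds to 0.424 and 0.191 CPM. Doublets were called per library with Scrublet in scanpy 1.11.5, which marked 1 meninges cell and 5 choroid plexus cells. These were kept in the reported values and removed in an alternative. So few calls among sorted cells of 1 kind do not measure the doublet rate, because doublets of like cells are not seen. Ambient RNA was not corrected.

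For the comparison of the libraries, counts were summed over cells, divided by the library total and given as CPM. Rows with a mean of at least 50 CPM were compared by their ratio, choroid plexus over meninges, and rows at least 2-fold apart were counted. Intervals of ratios are exact binomial intervals conditional on the sum of both counts, and intervals of shares are Clopper-Pearson intervals, all at 95%. For a share of 0, the limit given is 3 counts of the total. They cover counting error only and not differences between mice or libraries. With 1 library per tissue no test was made. For shares of cells and genes per cell at equal depth, each cell was thinned without replacement to 2000 UMIs and shallower cells were left out. The named rows are the 2 with the largest fold in each direction under the size rule.

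For clustering, counts were scaled to 10000 per cell and log transformed, and 2000 variable rows, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.5 were used (igraph 0.11.9), on both libraries together without integration and on each library alone. Clusters are numbered by falling size. To match clusters between libraries, the log2 ratio of CPM + 5 in a cluster over CPM + 5 in the other cells of its library was correlated across rows. Clusters were not named.

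On simulated data, 2 libraries drawn from the pooled profile at the real totals, the size rule recovered 100% of the rows changed 3-fold, called 0% of the rows changed 1.3-fold and 0 unchanged rows among 2245 tested. Clustering placed 98% of simulated cells with 100 raised rows in 1 cluster and left the cells drawn from 1 profile in 1 cluster. The simulated cells carry counting noise only.

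Before the data were examined, the designs, the size rule, the naming rule and most alternatives were fixed: the cell filter, removal of called doublets, thinning depth, TMM scaling (edgeR 4.0.16) and median-of-ratios scaling (DESeq2 1.42.0), the CPM floor, the fold, CPM averaged per cell, and the clustering settings. edgeR and DESeq2 gave scaling factors only. Alternatives added after the data had been seen left out 2 small clusters, left out the highest cell of each row, weighted clusters alike in both libraries (using joint clusters, or clusters of 1 library to which cells of the other were assigned by their 15 nearest neighbours in its principal components), or clustered without rows at least 1.5-fold apart. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.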

Results

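Group 2 innate lymphoid cells (ILC2) are lymphocytes without antigen-specific receptors that reside in tissues and secrete type 2 cytokines when they sense alarmins such as IL-33. The series profiled single ILC2 sorted from 2 tissues at the border of the brain in C57BL/6 mice aged 20 to 22 months. These were the choroid plexus, the epithelial tissue of the ventricles that secretes cerebrospinal fluid, and the meninges, the membranes around the brain. All mice had received IL-33 at 400 ng per day for 7 days. The series states its question as how gene expression differs between ILC2 of the 2 tissues. It holds 1 library per tissue, so the values below describe these 2 libraries, no test compares the tissues, and no p-value is given. No untreated or young library was analysed here.

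The meninges matrix held 1477 cell barcodes with 7128268 UMIs (unique molecular identifiers, each standing for 1 captured transcript), and the choroid plexus matrix held 2584 barcodes with 15796970 UMIs. Barcodes with at least 500 detected genes were kept, which left 1448 meninges cells and 2551 choroid plexus cells. Both matrices number their gene rows from 1 to 31053 and pair no names with them. Genes are therefore given by row number, clusters by number, and the identity of the cells as ILC2 rests on the sort that the labels describe. No gene or pathway could be named, so gene lists and cell type markers fixed before the data were examined were not used.

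Choroid plexus ILC2 yielded more RNA per cell. The median was 5378 UMIs per cell in the choroid plexus (95% order-statistic interval 5286 to 5488, counting cells only, n = 1 library) and 4260.5 in the meninges (4169 to 4357, n = 1 library), a ratio of 1.26. The median number of detected genes was 1699 in the choroid plexus and 1518 in the meninges. At equal depth the order turned. With every cell thinned to 2000 UMIs, meninges cells showed a median of 871 genes (interval 867 to 876) and choroid plexus cells 841 (838 to 844). Thinning left out 117 meninges cells and 107 choroid plexus cells that were shallower. The ratio of these medians, choroid plexus over meninges, was 0.966. With 1 library each, a difference in capture or sequencing between the libraries cannot be told apart from the tissue.

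Summed over cells, the expression profiles of ILC2 from the 2 tissues were close. Among the 2259 gene rows with a mean of at least 50 CPM (counts scaled to the library's total), the profiles correlated with a Pearson r of 0.95 on log2(CPM + 1) and a Spearman rho of 0.91. This correlation is across genes, which are not independent replicates. Of these rows, 91.2% lay within 1.5-fold of each other.

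By the size rule, a mean of at least 50 CPM and at least a 2-fold difference, 70 rows stood apart. Of these, 19 were higher and 51 lower in the choroid plexus. The median fold was 2.40 among the higher rows and 2.53 among the lower rows, and 6 higher and 10 lower rows were at least 4-fold apart. The balance of the directions depended on the scaling. With TMM scaling, which lifted the median log2 ratio of the tested rows from -0.01 to 0.17, 28 rows were higher and 34 lower. Median-of-ratios scaling also gave 28 and 34.

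Of the 70 rows, 39 also differed in the share of cells in which they were detected, and 3 had most of their UMIs in a single cell. A share of cells with a UMI that differed by at least 10 percentage points at 2000 UMIs per cell, in the same direction, was found for 12 of the 19 higher rows and 27 of the 51 lower rows. The lower rows were detected in a median of 20.2% of meninges cells and 9.66% of choroid plexus cells at that depth. The higher rows were detected in a median of 6.76% and 17.9%. In 3 of the 70 rows, 1 cell of the higher library held over 50% of that library's UMIs for the row.

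Row 19631 was the most widespread of the 4 rows that the naming rule picked, the 2 with the largest fold in each direction. It reached 442 CPM (6966 UMIs) in the choroid plexus and 58.1 CPM (411 UMIs) in the meninges, a 7.62-fold difference with an exact 95% interval of 6.90 to 8.44 that covers counting error only. The interval treats UMIs as independent, though 10 cells held 22.1% of the row's meninges UMIs. Within clusters 1, 2, 3 and 4 of both libraries together the gap was narrower, but these clusters are themselves drawn along the library difference. The choroid plexus had 447, 115, 485 and 398 CPM there, and the meninges 110, 29.2, 106 and 107. With the clusters found without differing rows weighted alike in both libraries, the row's log2 ratio was 2.82, against 2.93 with all cells. Row 19631 was detected in 1537 choroid plexus cells, 60.3% (Clopper-Pearson 95% interval 58.3 to 62.2%), and in 169 meninges cells, 11.7% (10.1 to 13.4%). Thinned to 2000 UMIs, the shares were 43.7% and 6.76%. The lowest share in any cluster of at least 20 cells was 1 of 59 cells, 1.69%, in a meninges cluster with a median of 2639 UMIs per cell. Among choroid plexus cells the lowest share was 21 of 89 cells, 23.6% (15.2 to 33.8%). No cell type known to lack the gene could be named as a background.

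In the other 3 named rows, most UMIs of the higher library came from 1 cell. Row 29626 had 3970 UMIs in the choroid plexus and 5 in the meninges, and 3406 of the 3970 came from a single cell. Without the highest cell of each library, 564 and 3 UMIs remained (35.8 and 0.424 CPM), a log2 ratio of 6.40 against 8.48 with all cells, and the row was then also under the 50 CPM floor. Its 10 highest cells held 99.1% of its choroid plexus UMIs, and its log2 ratio was 3.48 when the clusters found without differing rows were weighted alike. That weighting used the 5 of 6 clusters with at least 20 cells in each library. Cells of the remaining cluster dropped out, so the fall cannot be credited to the weights alone. Row 10911 had 1112 UMIs in the meninges and 1 in the choroid plexus, a ratio of 2474 with a counting interval of 443 to 97801, yet 1105 of the meninges UMIs lay in 1 cell and the row was detected in only 8 meninges cells. Row 13667 had 1438 UMIs in the meninges and 2 in the choroid plexus, a ratio of 1599.6 with a counting interval of 442 to 13221, and 1415 of the meninges UMIs lay in 1 cell. Without the highest cells, row 13667 had 23 and 1 UMIs, and row 10911 had 7 and 0, both also under that floor. Counting intervals assume independent molecules, so they are far too narrow for these 3 rows.

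**Figure D1:**
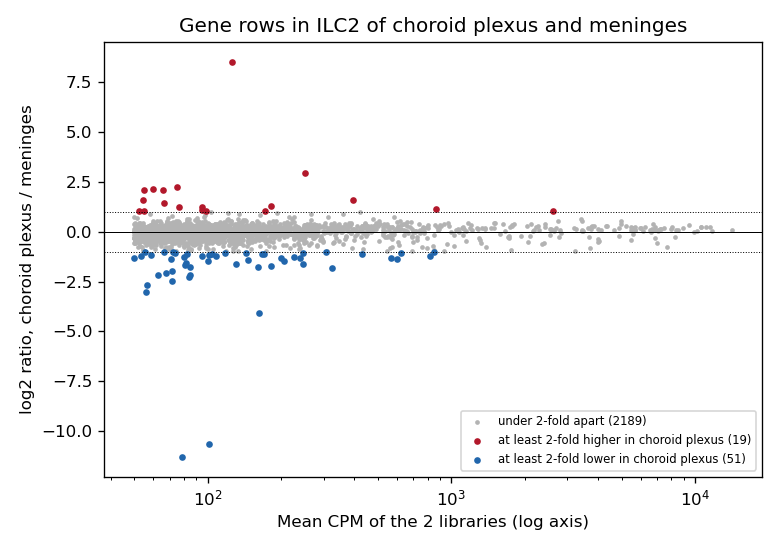
Each point is 1 gene row with a mean of at least 50 CPM; the x axis is the mean CPM of both libraries on a log axis and the y axis the log2 ratio of choroid plexus over meninges, with dotted lines at 2-fold. Most rows lie near 0, with 19 rows above and 51 below the lines, and the 3 most extreme points are the rows with most of their UMIs in a single cell.

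Each library held several clusters of cells, and the 2 largest meninges clusters each had a choroid plexus cluster with a similar profile. Clustered alone, the meninges library split into 4 clusters of 654, 474, 261 and 59 cells. The choroid plexus library split into 6 clusters of 974, 672, 565, 293, 37 and 10 cells. Clusters were matched by their log2 ratio against the other cells of the same library, across the 2259 rows. Meninges cluster 1 matched choroid plexus cluster 1 (Pearson r = 0.64, Spearman rho = 0.64) and cluster 4 (r = 0.58, rho = 0.56). Meninges cluster 2 matched choroid plexus cluster 3 (r = 0.73, rho = 0.54). With choroid plexus cluster 2 it had an r of 0.55 but a rho of only 0.33, and that cluster had only 3 rows at least 2-fold above and 6 below the other choroid plexus cells. Meninges cluster 2 itself had 3 rows above and 93 below the other meninges cells. Meninges clusters 1 and 2 made up most of each other's comparison cells, so their matches are not independent. Meninges cluster 1 had an r of -0.60 with choroid plexus cluster 3, and meninges cluster 2 of -0.53 with choroid plexus cluster 1. Meninges cluster 3, with a median of 5786 UMIs per cell, matched choroid plexus cluster 5 (r = 0.50, rho = 0.51), which had a median of 15042. All 18 meninges cells of joint cluster 6, a group with a median of 16251 UMIs in the clustering of both libraries together, lay in meninges cluster 3, and without them the match fell to an r of 0.27 (rho = 0.30). These correlations are across genes. With cluster labels shuffled among the cells of each library, the highest absolute r of any pair reached 0.16 at most over 100 shuffles. Shuffled groups are not made of like cells, so this value shows only what random groups give. It cannot show that matched clusters are the same cell state.

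Meninges cluster 4 matched none of the choroid plexus clusters. Its 59 cells made up 4.07% of the meninges library (Clopper-Pearson 95% interval 3.12 to 5.22%), and its highest correlation with any choroid plexus cluster was an r of 0.11 (rho = 0.16). Its median of 2639 UMIs per cell was below the 4260.5 of all meninges cells, yet it showed a median of 1083.5 genes at 2000 UMIs, against 856 to 887 in the other meninges clusters.

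**Figure D2:**
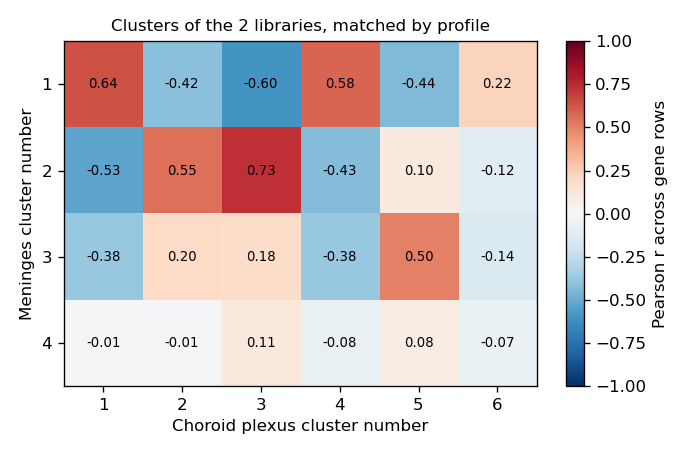
Each square gives the Pearson r, across 2259 gene rows, between a meninges cluster (y axis) and a choroid plexus cluster (x axis), each described by its log2 ratio against the other cells of its library. Meninges clusters 1, 2 and 3 each have a choroid plexus cluster at an r of 0.50 or more, which for cluster 3 falls to 0.27 without its 18 high-UMI cells, while meninges cluster 4 stays at 0.11 or below.

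When the cells of both libraries were clustered together without integration, 6 clusters formed, and how far cells sorted by library depended on the settings. Joint cluster 1 held 53.1% of choroid plexus cells (51.1 to 55.0%) and 13.5% of meninges cells (11.8 to 15.4%). Joint cluster 2 held 58.5% of meninges cells (55.9 to 61.0%) and 3.49% of choroid plexus cells (2.81 to 4.28%). Summing the smaller share of each cluster, the distributions overlapped by 40.9%. The overlap was 62.1% with 1000 variable rows, 52.6% at resolution 0.25, 51.1% at 2000 UMIs per cell, 46.7% without called doublets, 37.7% with 15 principal components and 32.6% at resolution 1.0. Because the rows behind these clusters also differ between the libraries, their sizes do not compare cell states between tissues. The clustering was therefore repeated without the 2317 rows that differed by at least 1.5-fold, a step chosen after the data had been seen. Leaving out the rows that separate the libraries raises the overlap by construction, here to 88.6%, so these clusters describe only the variation that the libraries share. The shares of the largest cluster were 51.0% of meninges cells (48.4 to 53.6%) and 42.9% of choroid plexus cells (41.0 to 44.9%). The next 2 clusters held 20.0% and 11.0% of meninges cells and 25.9% and 15.9% of choroid plexus cells, and the fourth held 12.9% and 13.4%.

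2 small groups stood out in the joint clustering. Joint cluster 5 consisted of the 59 cells of meninges cluster 4 and held 0 of 2551 choroid plexus cells, which allows a share of up to 0.118% (3 counts of the total). Without the differing rows the matching cluster held 52 meninges cells (3.59%) and 7 choroid plexus cells (0.274%). Joint cluster 6 held cells with a median of 16251 UMIs and 3430 genes. It made up 1.24% of meninges cells (18 cells, 0.738 to 1.96%) and 1.29% of choroid plexus cells (33 cells, 0.892 to 1.81%), with overlapping intervals. That cluster was not recovered with 15 principal components or at 2000 UMIs per cell.

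**Figure D3:**
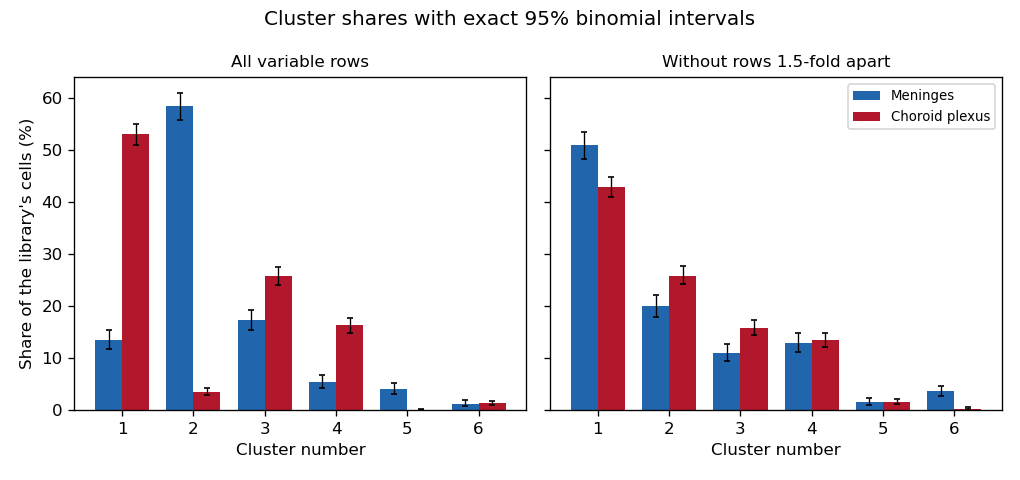
Bars give the share of each library's cells (%) in each joint cluster, with exact 95% binomial intervals that cover counting error only; the left panel used all variable rows and the right panel left out rows that differed by at least 1.5-fold, and the panels number their clusters separately. On the left, clusters 1 and 2 are dominated by 1 library each (53.1% against 13.5% and 3.49% against 58.5%), and on the right, where the rows that separate the libraries were removed, the shares lie closer, apart from the small cluster 6 (3.59% of meninges and 0.274% of choroid plexus cells).

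The 70 rows were also compared inside the clusters found without the differing rows. In the largest cluster found without the differing rows, all 19 higher and all 51 lower rows kept their direction, and 19 and 43 of them stayed at least 2-fold apart. In the second, 17 of the 19 higher and 51 of the 51 lower rows kept their direction, with 9 and 38 at 2-fold or more. In the third, all 19 and all 51 kept it, with 14 and 32 at 2-fold or more. In the fourth, 19 and 48 kept it, with 14 and 20 at 2-fold or more. In the fifth, 18 and 44 kept it, with 13 and 28 at 2-fold or more. With these 5 clusters weighted alike in both libraries, 91.1% of the median log2 ratio of 1.33 remained, with each ratio taken in its row's own direction. All 70 rows kept their direction, and 54 of them stayed at least 2-fold apart. The count depended on the clusters: it was 21 with joint clusters that keep the differing rows, 40 with the clusters of the meninges library and 49 with those of the choroid plexus library, to which the cells of the other library were assigned. These rows were picked on the same cells, so their direction within clusters is not independent evidence.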

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

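With 1 library per tissue, no library could be left out. No paired analysis was possible because each tissue has 1 library. The gene list alternatives were not run, because rows carry no names. Of 116 values of the main results recomputed under another setting, 77 stayed the same (a count within 1.5 times, other values within the counting interval) and 39 moved. These are counts, medians and shares with no sign of their own. Each count was judged alone, so a shift in the balance of directions can pass as the same. The 28 higher and 34 lower rows under TMM scaling did so against 19 and 51. The added settings, chosen after seeing the data, were those that leave out clusters or each row's highest cell, weight clusters alike, or cluster without differing rows. A minimum of 1000 genes moved the median UMIs to 4497 in the meninges and 5542 in the choroid plexus, and the median genes to 1566 and 1727. The genes at equal depth followed the depth chosen, 523 and 509 at 1000 UMIs and 1425 and 1373 at 4000, and the meninges value stayed the higher. Rows higher and lower in the choroid plexus numbered 63 and 140 at a CPM floor of 10, 4 and 14 at a floor of 200, 47 and 152 at 1.5-fold, and 384 and 4075 with no floor. The last split follows from its construction, since 3 counts are worth 2.22 times more CPM in the shallower meninges library. All 19 higher and 34 of the 51 lower rows still met the size rule under TMM scaling. Weighting clusters alike gave 8 higher and 12 lower rows with joint clusters that keep the differing rows (8 and 10 of them among the 70), and 13 and 23 with the clusters of the meninges library (13 and 21 among the 70). Rows that also differed in the share of cells fell to 5 and 16 when thinned to 1000 UMIs and to 4 and 6 with a required gap of 20 percentage points. The overlap of cluster shares was 52.6% at resolution 0.25, 32.6% at 1.0 (with 12 joint clusters), 62.1% with 1000 variable rows, 37.7% with 15 principal components, 51.1% at 2000 UMIs, 46.7% without called doublets and 88.6% without differing rows, where the meninges-only cluster held 0.274% of choroid plexus cells. The high-UMI cluster was not recovered with 15 principal components or at 2000 UMIs. The cluster nearest to it was larger there, with 14.7% of meninges and 14.2% of choroid plexus cells, and 10.1% and 44.1%, respectively. These shares therefore do not measure the high-UMI cells. The choroid plexus library alone gave 3 clusters at resolution 0.25 and 10 at 1.0, and the meninges library 8 at 1.0, so the number of states depends on the resolution. Why the overlap and the high-UMI cluster moved was not tested. Cells under 2000 UMIs did not enter the shares.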

Other observations

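The most abundant transcripts took a larger part of the RNA in choroid plexus ILC2. Among the 135 rows with a mean of at least 1000 CPM, 72.6% were higher in the choroid plexus, with a median log2 ratio of 0.11, and together they held 56.0% of its UMIs against 53.7% in the meninges. Among the 4612 rows from 10 to 50 CPM, 28.3% were higher in the choroid plexus, with a median log2 ratio of -0.17. The 100 most abundant rows held a median of 51.3% of a choroid plexus cell's UMIs (quartiles 48.6 and 53.9%) and 49.3% of a meninges cell's (46.1 and 52.0%). The rows above 1000 CPM held a larger median share in the choroid plexus in each of the 5 clusters shared by both libraries, from 53.8% against 53.2% in the second to 50.2% against 46.2% in the fifth. Under TMM scaling, which moves every log2 ratio up alike, the medians became 0.29 above 1000 CPM and 0.00 from 10 to 50 CPM, so only the contrast between abundant and scarce rows is independent of the scaling.

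Choroid plexus cluster 6 held 10 cells (0.392% of the library) with a median of 1600.5 UMIs. Its closest meninges cluster was cluster 1 (r = 0.22, rho = 0.31), and all 10 cells fell into joint cluster 4. Of the barcodes left out for having fewer than 500 genes, 11 of 29 in the meninges had 1 row with at least 50% of their UMIs, against 1 of 33 in the choroid plexus, and 1 of the leading rows was shared by both libraries. In 13 and 18 of these barcodes, respectively, 1 row held at least 10% of the UMIs.

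Of the tests that follow, those on doublets, damage and the mix of clusters were chosen after their result or related values had been seen, and the one on a part of the cluster's cells was added later. Those on shallow cells, deeper capture and cells matched for UMIs were also added later, with bounds set before their values were seen. The one on deeper capture replaced a count of rows at least 2-fold above the sum of all other cells, which was 344 and known when its bounds were set.

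The first pattern is the cluster of 59 meninges cells with 0 choroid plexus cells, in which 168 rows with at least 50 CPM were at least 4-fold above every other joint cluster. Low depth alone is argued against, since 191 meninges cells as shallow as the cluster's median lay in other clusters. With every cell thinned to 2000 UMIs, the cluster nearest to it still held 3.38% of meninges cells. The summed CPM of the 168 rows was 0.17 higher on the log2 scale in those shallow cells than in deeper ones, against 3.99 in the cluster. These last 2 values cannot decide, because the rows were picked as high in the cluster and clustering had already set such cells apart. Full counterparts hidden in other choroid plexus clusters are argued against too: 0 of 2551 cells reached the cluster's 10th percentile of UMI share in its 20 leading rows (0.220%), and with rows and cutoff from 30 of its cells, 20 of its 29 remaining cells did and again 0 choroid plexus cells. The 7 choroid plexus cells that joined it without the differing rows had a median share of 0.0413%, against 0.442% in the cluster and 0 in all choroid plexus cells, and 1 of them had the highest share (0.154%), so a partial counterpart stays open. Damage, which can also raise rows, another cell type passing the sort in that library, and a kind of cell found in the meninges may each account for it, and gene names and a second library would be needed to test them.

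The second pattern is the cluster with a median of 16251 UMIs per cell, present at 1.24% and 1.29% of the libraries. Doublets of cells typical of the other clusters cannot exceed the CPM of their parts, yet 108 rows were at least 4-fold above every other cluster. The comparison was with the CPM of whole clusters, so it does not cover doublets with a kind of cell that is rare within them. Deeper capture of ordinary cells could account for the cluster's loss at 2000 UMIs per cell. There the cluster nearest to it held 10.1% of meninges and 44.1% of choroid plexus cells. Cells in both clusters made up 3.69% of the cells in either. The size of the larger cluster keeps this value low even if the high-UMI cells stayed together inside it. An earlier test on genes per cell at that depth gave a ratio of 1.09 to the other cells, between the bounds set for it. Yet deeper capture alone would leave the CPM profile alike, and 321 rows raised at least 2-fold in choroid plexus cluster 5 had a summed CPM 1.502 higher on the log2 scale (95% interval 1.137 to 1.785 over resampled cells) in the 18 meninges cells with the most UMIs, picked by UMIs alone and 10 of them in the cluster, than in meninges cells of 4000 to 6000 UMIs, and 14 of the 18 still lay above the 95th percentile of those cells when thinned to 2000 UMIs. Doublets that include a cell type absent from the other clusters or rare within them remain possible, and a cell state with more RNA stays open as an untested hypothesis.

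The third pattern is the set of 70 rows at least 2-fold apart between the libraries. Without both small clusters 82.9% of the rows still met the size rule. In cells of 4000 to 6000 UMIs (502 meninges and 1100 choroid plexus cells), 93.7% of the median log2 ratio, taken in each row's own direction, was left. There 54 of the 70 rows stayed at least 2-fold apart. All 70 kept their direction, but they were picked on the same cells. These values argue against the small clusters or the UMIs per cell as the whole cause. A different mix of cell states stays open: with clusters weighted alike, 57.5% of the median log2 ratio of 1.33 was left with joint clusters that keep the differing rows, 84.8% with clusters of the meninges library and 93.2% with those of the choroid plexus library, but the joint clusters are themselves drawn along the library difference. An earlier test with the clusters found without the differing rows left 91.1%, with 68.6% of the rows within the size rule, between the bounds set for it, and leaving out those rows limits what it can show. The tissue, as an untested hypothesis, and any other difference between these 2 libraries cannot be told apart, since each tissue has 1 library.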
